A study of Zea mays with 6 samples.

How the data were processed

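RNA was sequenced from young leaf and from seedling of maize plants with and without Dp3a, a chromosome fragment that carries a de novo centromere, a centromere formed at a site that did not hold one before. Chromatin bound by CENH3, the histone H3 variant of centromeres, and by histone H2A phosphorylated at threonine 133 (ph-H2A-T133) was immunoprecipitated from Dp3a young leaf and treated with bisulfite before sequencing. There were 4 RNA libraries and 2 bisulfite libraries, 1 library per group.

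The submitters' processing notes name CASAVA, TopHat2 2.0.12, Cufflinks and Cuffdiff for the RNA and BS-Seeker2 with Bowtie2 for the bisulfite reads, and B73 RefGen_v3 as the genome build. Their settings are not given in the sources used here. The authors deposited FPKM values (fragments scaled to transcript length and library depth) for control and Dp3a, per the file headers, in 1 Cuffdiff table per tissue. Each table also holds the authors' p-value and q-value per locus, per the file headers. For the CENH3 library the authors deposited a methylation map on the named build, with the count of methylated calls, the count of all calls and the methylated fraction per cytosine, per the file headers. The fraction differed from the ratio of the counts by more than 0.01 in 0 lines. For both antibodies the authors deposited intervals of 10 to 400 bp without score or strand, and what an interval stands for (a read, a fragment or part of one) is not stated. The last intervals of chromosomes 8 and 10 end 446768 and 561817 bp beyond the last cytosine of the map. The intervals were therefore treated as lying on another build, were analysed apart from the map, and no coordinate was carried between them.

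The design was written for aligned reads. In place of read density, CENH3 density was the number of cytosine calls of the map per 50 kb window, and the ph-H2A-T133 comparison used interval midpoints per 50 kb window in both interval files. The map was chosen over the CENH3 interval file as the source of domains after both had been seen, because the map shares its build with the expression tables. A domain was a run of windows at 5 times the chromosome's median window or more, joined across gaps of up to 100 kb and at least 150 kb long. The native centromere of a chromosome was its domain with the most calls, and a further domain on chromosome 3 was taken as the de novo domain, from the CENH3 library alone. Density was not divided by an input library, which was not used here.

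Methylation was the share of methylated calls over cytosines with 4 or more reads, per sequence context, with exact Clopper-Pearson intervals at 95 percent. These intervals cover counting error only, since calls on 1 read are not independent and PCR copies could not be removed. The de novo domain was set against flanks of 1 Mb on either side and against 10000 random placements of the same length on chromosome 3 outside its native centromere. Native centromeres were set against their own flanks of 1 Mb by a two-sided exact sign-flip permutation over chromosomes of the 1 library, with Benjamini-Hochberg adjustment over the 3 contexts. Plastid cytosines were planned as the measure of non-conversion, but their level differed between contexts, so they are only described.

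For expression, a locus was counted in a tissue with status OK and FPKM of 1 or more in either library. Its ratio was the log2 of Dp3a FPKM plus 1 over control FPKM plus 1, and 2-fold loci were those at 1 or beyond on that scale in either direction. No p-value was computed, since each group held 1 library. Gene lists were described by their median ratio, with a bootstrap interval over members (2000 draws), and by the percentile of that median among 10000 random lists of the same size drawn within 20 strata of mean expression. Lists with fewer than 3 counted loci got no percentile. The percentiles describe these libraries and are not p-values. The 16 lists were C4 photosynthesis, light harvesting, anthocyanin pathway, heat shock and chaperones, defence and pathogenesis-related, jasmonate and wound response, DNA methylation and silencing, centromere and kinetochore, core and linker histones, cell cycle and DNA replication, circadian clock, cell wall expansion, nitrate and phosphate uptake, and 3 lists of other tissues, seed storage, root, and anther and pollen. Members are loci, so a gene ID with a locus on each strand counts at both, and reads from such a pair cannot be told apart without strand. One ID of the DNA methylation list, GRMZM2G071025, was left out because its symbol in the name table contradicted its name in the list. That was decided after values had been seen.

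The named genes follow a rule fixed before the data were examined, as were the lists, thresholds and tests unless stated otherwise. Per tissue, the rule takes the 8 counted loci with the largest and the 8 with the smallest ratio, the 8 largest and 8 smallest among those with a symbol or informative description, and up to 4 members of each list by absolute ratio. Across tissues it takes the 8 highest and 8 lowest among loci at least 2-fold the same way in both. Every locus that overlaps the de novo domain with FPKM of 1 or more in any RNA library is also named. GRMZM2G005715 and XLOC_092049 were named outside that rule, for their place among the authors' calls. Symbols came from a RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. Of 39498 gene IDs in the expression tables, 18603 matched that table and 2401 of these had a symbol other than a clone or locus name. A further 62034 loci carried no gene ID.

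Expression along the genome was the median ratio of loci with FPKM of 1 or more in both libraries, in 5 Mb bins with 10 or more such loci. Runs of low loci, a comparison added after the data had been seen, were stretches of 20 neighbouring loci, 1 per span, with FPKM of 1 or more in the reference library of the tissue. A locus was low if the other library held less than 10 percent of that value, and low loci were shuffled 1000 times within expression strata.

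The steps were tested on simulated data before use. In the leaf comparison, with 22883 simulated loci, the 2-fold threshold called 23% of loci changed by a true fold of 2, 100% of those changed 4-fold and 100% of those changed 8-fold, and 0% of unchanged loci. The noise put on the simulated loci was set far below a 2-fold change. The 0% follows from that setting and gives no error rate for the real libraries. In the list comparison for leaf, over 23859 loci, 4.5% of 200 lists without a shift and 100% of 200 lists shifted by 1 fell outside percentiles 2.5 to 97.5. In the CENH3 domain comparison, over 4645 windows, 200 of 200 planted domains were recovered. They were planted at 8 times the median, above the threshold, among windows capped below it, so this recovery checks the code only. In the de novo domain methylation comparison, over 47039 cytosines, 96% of the intervals of 300 regions held the level they were drawn from. Calls were drawn independently at a single level, so this share checks the code only. It gives no error rate for the real calls, which are not independent.

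Alternatives to the pseudocount, expression filter, fold threshold, centring, domain threshold, window size, coverage minimum, weighting of cytosines, flank length and bin size were run. Others were added after the data had been seen. They leave out short loci, loci at 0, organelle loci or loci without a gene ID, count 1 locus per gene ID or per span, count every locus in the runs, use another density measure or the interval file for the domains, pick native centromeres in windows of 20 or 100 kb, or bin loci with FPKM of 1 or more in either library. The 765567 lines of the map on unplaced scaffolds were not used, and methylation in the ph-H2A-T133 library was not analysed here. Cuffdiff's own log2 ratios were not used, as some of their cells were not numbers, and ratios were recomputed from FPKM. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9, with random seed 1.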

Results

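Expression was measured by RNA sequencing in young leaf and seedling of maize plants with and without Dp3a, and CENH3 and ph-H2A-T133 chromatin was profiled by immunoprecipitation and bisulfite sequencing in Dp3a young leaf. Each of the 6 groups held 1 library, so no difference between control and Dp3a below has a replicate check. The read depth of the RNA libraries is unknown, because FPKM values carry no read counts. The FPKM values summed to 1200065 in control leaf, 1249117 in Dp3a leaf, 1801022 in control seedling and 7067513 in Dp3a seedling. Loci shorter than 300 bp held 27.0% of the sum in each leaf library, 59.8% in control seedling and 89.2% in Dp3a seedling. The methylation map of the CENH3 library held 189135588 cytosines, 57.4% of them covered by 1 read and 10.03% by 4 or more. The interval files held 8130840 intervals for CENH3 and 8829369 for ph-H2A-T133. Coordinates of genes and of the map are those of B73 RefGen_v3.

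The first question was where CENH3, which marks the active centromere, lay on the chromosomes of Dp3a plants. On chromosome 3 the map showed CENH3 at the native centromere, 100250001 to 100750000, at 8.91 times the chromosome's median window, and at a separate domain on the long arm, 219050001 to 219250000, at 8.05 times. This domain of 200 kb held 239269 cytosine calls, against 662047 in the native centromere, and its 50 kb windows from left to right stood at 10.8, 8.11, 6.75 and 6.59 times the median. To its left the neighbouring windows stood at 3.33, 3.51 and 4.89 times moving outward, and to its right the next window stood at 1.66 times. Native centromeres were called on 9 chromosomes, none on chromosome 2, the densest on chromosome 10 (48250001 to 49450000) at 11.6 times.

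**Figure D1:**
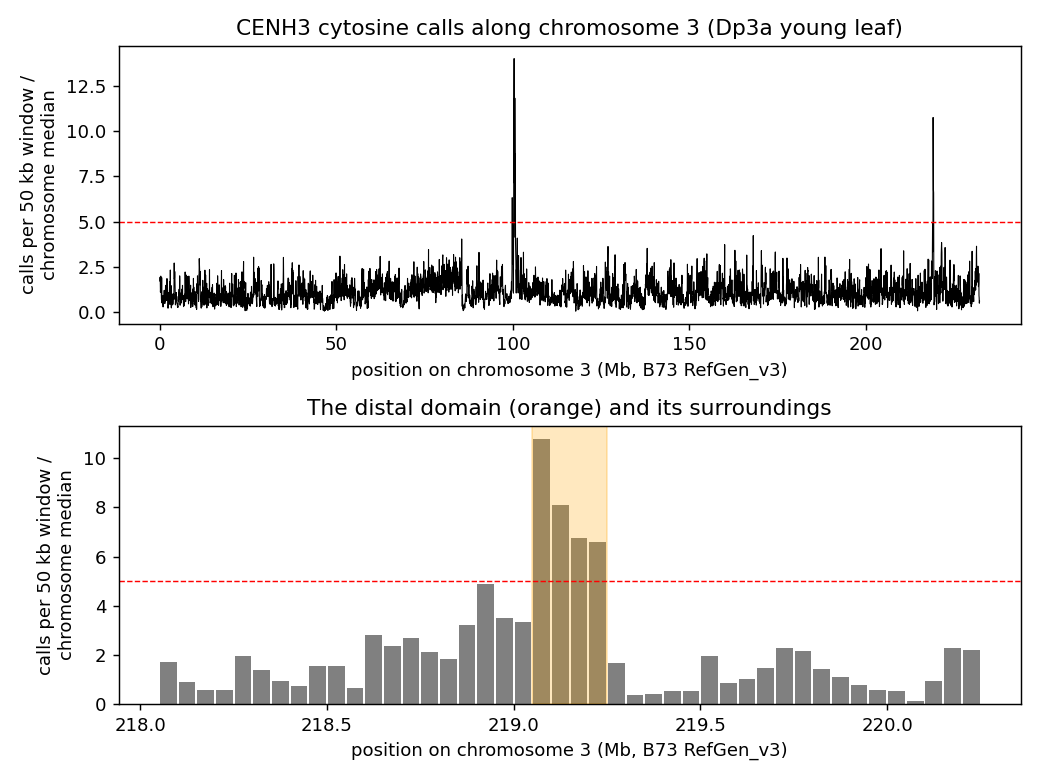
CENH3 density along chromosome 3 of Dp3a young leaf, as cytosine calls per 50 kb window over the chromosome's median window, by position in Mb (top, whole chromosome with the threshold of 5 dashed; bottom, the region around the de novo domain, in orange). The native centromere averages 8.91 and the de novo domain 8.05, with a highest window of 10.8.

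Further stretches of dense calls lay outside the native centromeres. Besides the de novo domain there were 12 such domains, the densest on chromosome 6 at 20450001 to 20650000 (37.5 times its median) and 39150001 to 39300000 (18.6 times), and 1 at the tip of chromosome 10, 1 to 500000 (9.21 times). Of 41198 windows, 228 reached 5 times the median, or 0.553%. The de novo domain was called at thresholds of 3 and 5 times but not at 10 times, where its length was 0 kb, and at 3 times chromosome 3 held 1 more domain, 221350001 to 221600000, at 3.51 times. By mean reads per covered cytosine, a measure chosen after seeing the data, the folds were smaller. Called at 2 times the median, the de novo domain then stood at 2.18 times over 400 kb. The native centromere of chromosome 3 stood at 2.53 times. No input library was used here, so a repeat whose copies are collapsed in the reference also counts as dense.

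Histone H2A phosphorylated at threonine 133 was set beside CENH3 to ask whether both marks were dense over the same regions. On the build of the interval files, both were enriched over the native centromere of chromosome 3, 100200001 to 100750000, CENH3 at 5.89 times and ph-H2A-T133 at 5.35 times the chromosome's median. Over the 7 native centromeres called in the interval file the median was 6.50 times for CENH3 (range 5.08 to 9.17) and 5.39 times for ph-H2A-T133 (range 3.99 to 8.99), with the higher value for ph-H2A-T133 in 2 of them. Across 41176 windows, which are not independent replicates, the densities of both marks had a Spearman rho of 0.961. Most of these windows lie outside any domain, and no input library was used. The rho therefore cannot tell marks that share regions from uneven density common to both libraries. The interval file held 0 further domains on chromosome 3 at 5 times the median. At 3 times it held 4, at 81700001 to 81900000, 174200001 to 174350000, 219000001 to 219150000 and 221300001 to 221500000, all on its own build. The stretch that starts at 219000001 stood at 3.53 times for CENH3 and 3.01 times for ph-H2A-T133, and the one that starts at 221300001 at 3.51 and 3.42 times. The one that starts at 81700001 stood at 2.77 times for CENH3 and 3.50 times for ph-H2A-T133, and the one that starts at 174200001 at 2.68 and 2.59 times. By the rule of most intervals, the pick in this file would have been the stretch that starts at 221300001, with 2443 intervals. With 20 kb windows the count of further stretches was 21.

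DNA methylation was compared between the de novo domain and the chromatin beside it. In Dp3a young leaf the domain was more methylated in the CG context than its flanks of 1 Mb, 92.5% (95% interval 92.3 to 92.7) against 86.4% (86.2 to 86.7), a difference of 6.07 points (5.73 to 6.42). CHG methylation was lower in the domain, 69.3% (68.9 to 69.7) against 72.5% (72.1 to 72.9), a difference of -3.20 points (-3.80 to -2.60). CHH methylation was lower too, 1.88% (1.79 to 1.98) against 2.59% (2.47 to 2.70), a difference of -0.705 points (-0.854 to -0.556). The native centromere of chromosome 3 stood at 93.4% CG, 70.3% CHG and 1.65% CHH, and chromosome 3 as a whole at 86.3%, 72.4% and 2.27%.

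The flanks differed from each other. The left flank, 218050001 to 219050000, held 88.2% CG, 73.3% CHG and 2.27% CHH methylation, and the right flank, 219250001 to 220250000, held 82.5%, 70.8% and 3.29%. Among 10000 random placements of the domain on chromosome 3, its CG level lay at percentile 79.1, its CHG level at 31.9 and its CHH level at 30.9, so none of the levels stood outside the range of other stretches. Mean coverage was 8.73 reads per CG cytosine in the domain and 6.11 in the flanks. The differences depended on coverage and flank length, with a CG difference of 3.67 points against flanks of 500 kb, a CHG difference of -1.10 points at 1 or more reads and a CHH difference of -0.218 points at 8 or more reads. No methylome of control plants was used here, so these values compare regions of Dp3a plants only. The library was immunoprecipitated with CENH3. Calls in the dense domain and in its flanks may therefore come from unlike chromatin or unlike copies of chromosome 3. These were not separated, so the differences may not be between regions alone.

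**Figure D2:**
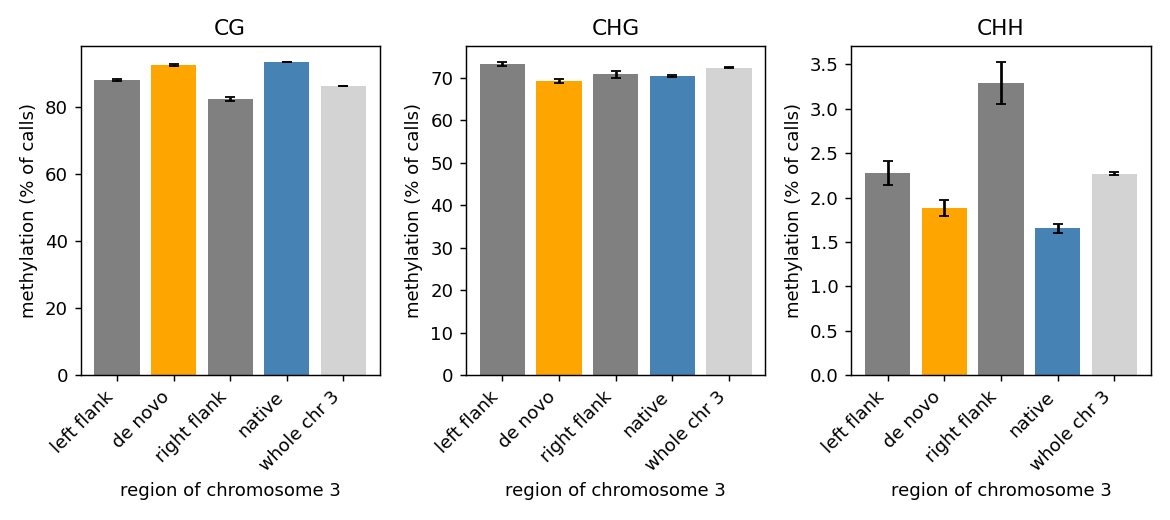
Methylation in percent of calls in the CG, CHG and CHH contexts (1 panel each) over the left flank, the de novo domain, the right flank, the native centromere and all of chromosome 3 in the CENH3 library of Dp3a young leaf. Error bars are exact 95% intervals of counting error; the de novo domain stands at 92.5% CG and the native centromere at 93.4%.

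Native centromeres were set against their own flanks in the same way, with the same limit on which chromatin the library sampled. They were more methylated in CG than the flanks on 9 of 9 chromosomes, by a mean of 1.99 points (SD 1.16, n = 9), and less methylated in CHH on 8 of 9, with a mean difference of -0.277 points (SD 0.158). CHG methylation was lower on 8 of 9 chromosomes, with a mean difference of -3.73 points (SD 6.05), with chromosome 9 at -18.4 points and chromosome 1 the exception at 2.76 points. The stretch picked as native centromere of chromosome 9, 73200001 to 73550000, held 52.9% CHG methylation, against 71.4% in its flanks. By the two-sided exact sign-flip permutation over the 9 chromosomes, p was 0.0039 for CG (adjusted 0.0117), the smallest it can give, 0.0391 for CHG (adjusted 0.0391) and 0.0078 for CHH (adjusted 0.0117).

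The size of the CHG difference depended mostly on chromosome 9. Without it the mean was -1.90 points (exact p = 0.0781, n = 8). Leaving out any other chromosome kept the mean between -4.55 and -3.36 points. With 8 chromosomes left, the exact p was 0.0078 without chromosome 1, 0.0469 without chromosome 8, and between 0.0625 and 0.0781 without chromosome 3, 4, 5, 6, 7 or 10. At 8 or more reads the mean CHG difference was -0.429 points and no longer passed the test. In the interval file, on its own build, the chromosome 9 pick at 5 times the median was 67150001 to 68100000, at 9.17 times. At 3 times, that file held no chromosome 9 stretch between 72200000 and 74750001. The map's pick was 73200001 to 73550000. No coordinate was carried between the builds, so whether that stretch is dense in the interval file cannot be told. The pick on chromosome 9 also depended on window size, a check made after seeing the data. With 20 kb windows the stretch with the most calls was 68140001 to 68800000, at 69.4% CHG and -4.44 points, and over the 10 chromosomes then called the mean CHG difference was -2.60 points (SD 2.69, exact p = 0.0137) and the CG difference 1.20 points (exact p = 0.0918, n = 10). With 100 kb windows, where the pick on chromosome 9, 73200001 to 73600000, overlapped the first, the means were -3.19 points in CHG (exact p = 0.0742, n = 9) and 1.90 in CG (exact p = 0.0039, n = 9). Over every cytosine with 1 or more reads, unlike the region values above, the genome levels over chromosomes 1 to 10 were 86.2% CG, 72.3% CHG and 2.36% CHH. By the same minimum, plastid DNA stood at 3.99%, 3.20% and 0.710%, so its level differed by context and no single rate of non-conversion is given.

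Young leaf of Dp3a and control plants was compared to ask which genes differ with the extra chromosome. Genes of the defence list were mostly higher in Dp3a leaf, genes of the cell wall list were lower, and genes of the jasmonate list went both ways with a median below 0. PR-1 (GRMZM2G465226), a pathogenesis-related protein, had 0.276 FPKM in control and 49.6 in Dp3a leaf (log2 ratio 5.31), and a chitinase (GRMZM2G453805), of the enzymes that degrade the chitin of fungal walls, had 16.8 and 129. The beta-expansin expB2 (GRMZM2G021621), of the proteins that loosen grass cell walls, had 11.7 in control and 1.47 in Dp3a leaf (log2 ratio -2.37). The allene oxide synthase aos2 (GRMZM2G002178), which acts in jasmonate synthesis, had 15.8 and 2.08 (log2 ratio -2.45).

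Of 23859 counted loci in leaf, 1287 were at least 2-fold higher and 1504 at least 2-fold lower in Dp3a, and 88.3% lay within 2-fold. Across loci, which are not independent replicates, the log2 values of both libraries had a Pearson r of 0.873. Among loci with a gene ID, 700 were higher and 950 lower. Other genes with a symbol that were higher in Dp3a leaf were sdh1 (145 and 649 FPKM in control and Dp3a), the glutathione S-transferase gst41 (9.31 and 43.0), NAR (0.671 and 7.74), PYL5 of the abscisic acid receptor family (0.322 and 3.45), the chitinase chiI (53.6 and 179.8) and ERTC (3.57 and 13.9). Lower were inra2(prp) (26.5 and 0.120), bHLH116 (9.13 and 0.712), the vacuolar invertase ivr2 (69.4 and 11.6), the glutathione S-transferase GST38 (8.42 and 0.749) and BURP4 (289 and 53.4). The squalene synthase sqs1 (GRMZM2G108225), of sterol synthesis, had 481 FPKM in control leaf and was listed at 0 in Dp3a leaf, with 1403 and 1229 in the seedling libraries.

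The largest ratios of all in leaf came mostly from loci of about 100 bp without a gene ID, which were listed at 0 in 1 of the libraries. XLOC_035997 (chromosome 2) was listed at 0 in control and at 23751 FPKM in Dp3a leaf, followed by XLOC_015600 (13137), XLOC_083545 (4099.6), XLOC_088016 (4098), XLOC_023105 (2718), XLOC_088015 (2434) and XLOC_059128 (2132). XLOC_047207 (chromosome 3) had 20202 FPKM in control leaf and was listed at 0 in Dp3a leaf, followed by XLOC_059359 (14518), XLOC_088028 (11927), XLOC_097285 (6647), XLOC_070574 (4002), XLOC_088201 (3601), XLOC_059551 (2366) and XLOC_015632 (1753). A gene among them, GRMZM5G895106 (chromosome 4), had 0.459 FPKM in control and 4518 in Dp3a leaf, and the opposite order in seedling, 6178 and 0.415. An FPKM of exactly 0 can be a failed estimate, and 122 loci were listed at 0 in control leaf alone and 142 in Dp3a leaf alone while they had 1 or more in each of the other 3 libraries.

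In the authors' deposited table, 24 leaf loci were called significant. Of the loci called in the authors' deposited table for leaf, 21 were listed at 0 in control and 1 (GRMZM2G005715) at 0 in Dp3a, and 12 of the 21 had 1 FPKM or more in control seedling. The other 2 in the authors' deposited table were C4 genes, the PEP carboxylase pep1 (GRMZM2G083841) at 6355 and 7594 FPKM and the pyruvate phosphate dikinase C4ppdkZm1 (GRMZM2G306345) at 10802 and 10661.

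Of the 12 fixed lists with a percentile in leaf, 4 lay outside the central 95% of random lists. Cell wall expansion had a median log2 ratio of -1.76 (percentile 0.00), with 8 of 8 counted loci below 0 and 6 at least 2-fold lower, among them expB6 (47.9 and 10.8 FPKM in control and Dp3a), expB5 (18.4 and 3.88) and expB8 (30.2 and 7.69). Defence and pathogenesis-related had a median of 1.43 (percentile 100), with 5 of 8 loci at least 2-fold higher, among them chiA (0.206 and 2.84), and 1 at least 2-fold lower, prp2 (5.63 and 1.10). Jasmonate and wound response had a median of -0.32 (bootstrap interval -0.81 to 0.01, percentile 0.22), with 9 of 26 loci above 0 and 7 at least 2-fold lower, among them TIFY28 (4.49 and 0.587) and the lipoxygenase lox6 (410.2 and 177), and 1 higher, TIFY20 (1.81 and 5.69). The anthocyanin pathway had a median of -0.50 (percentile 2.11) over 7 loci that went both ways. Its regulator c1 had 40.3 and 10.7 FPKM and the chalcone synthase whp 36.6 and 14.0, while R-S had 0.380 and 3.01 and bronze-2 had 0.186 and 1.69. With a pseudocount of 0.1 the anthocyanin percentile was 3.72 and the list no longer stood outside, and with a filter of 5 FPKM the median was -0.91 over 4 loci.

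The remaining lists lay inside that range in leaf. C4 photosynthesis had a median of -0.02 (percentile 32.2, 7 loci), with the Rubisco small subunit rbcS at 5818 and 7174 FPKM, the phosphoenolpyruvate carboxykinase GRMZM2G001696 at 1516 and 1357 and the carbonic anhydrase GRMZM2G348512 at 747 and 681. Light harvesting had a median of 0.25 (percentile 85.1), with 4 of 4 loci above 0, CP24 (2581 and 3454), lhcb5 (1876 and 2395), lhcb4 (435 and 484) and Cab-m7 (7745 and 8181). Plastid-encoded loci had a median of 0.69 over 15 loci in the same libraries. Heat shock and chaperones had a median of 0.10 (percentile 74.4, 6 loci), with hsp22 at 165 and 305 FPKM and hsp18 at 1.61 and 0.556. DNA methylation and silencing had a median of 0.20 (percentile 87.0, 4 loci), with argonaute1 at 12.9 and 18.2 and met4 at 5.02 and 6.86. Centromere and kinetochore had a median of 0.12 (percentile 75.9, 4 loci), with the loci of cenH3 itself at 3.82 and 4.07 (GRMZM2G157596) and 1.05 and 1.37 (GRMZM2G158526), and the kinetochore gene MIS12-1 at 2.61 and 1.10. Core and linker histones had a median of -0.09 (percentile 34.9, 4 loci), or -0.26 with a filter of 5 FPKM, with his2a1 at 22.6 and 17.5. The circadian clock had a median of 0.01 (percentile 54.0, 6 loci), with GI at 119.6 and 106. Nitrate and phosphate uptake had a median of -0.33 (percentile 7.29, 7 loci), with pht6 at 1.55 in control and listed at 0 in Dp3a, and NNR1 at 34.3 and 56.8. That median turned to 0.21 over the 4 loci left by a filter of 5 FPKM. No locus of the cell cycle and DNA replication list was counted in leaf. Of the lists of other tissues, oleosin had 1.59 and 1.08 FPKM, the root hair gene rth3 1.49 and 1.16, Profilin 4.23 and 6.27 and DBB11 3.91 and 3.84.

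**Figure D3:**
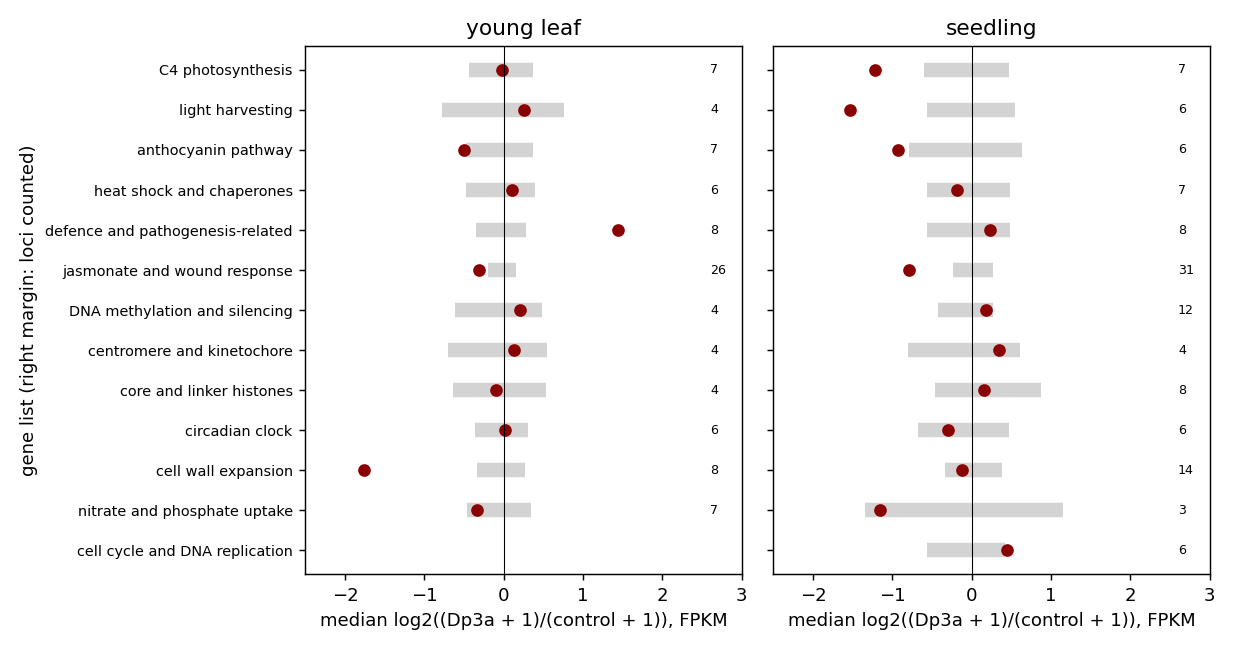
Median log2 ratio of Dp3a over control (dots) of each fixed gene list in leaf and seedling (1 panel each), with the central 95% of 10000 random lists matched on expression (grey bars) and the number of loci counted at the right. In leaf, cell wall expansion (-1.76) and defence (1.43) lie outside their bars; in seedling, light harvesting (-1.53), C4 photosynthesis (-1.22) and jasmonate (-0.79) lie below theirs.

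Seedling libraries were compared with the same question. Loci of the light harvesting list were lower in Dp3a seedling, and those of the C4 photosynthesis and jasmonate lists were mostly lower. The lipoxygenase lox10 (GRMZM2G015419), which makes oxylipins in leaves, had 1102 FPKM in control and 78.9 in Dp3a seedling (log2 ratio -3.79), and TIFY25 (GRMZM2G116614), of the family of jasmonate ZIM-domain repressors, had 27.9 and 0.899 (log2 ratio -3.93). The pyruvate phosphate dikinase C4ppdkZm1 had 44.4 and 1.07 (log2 ratio -4.46), and Rubisco activase RA (GRMZM2G162200) had 31.3 and 2.06 (log2 ratio -3.40). Higher in Dp3a seedling were NAC79 (0.768 and 20.1), JMJ13 (2.53 and 42.6), inra2(prp) at both of its loci (35.9 and 412; 2.27 and 30.1), the glutathione S-transferase gst42 (0.543 and 10.9) and GP (11.6 and 92.2).

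Of 28083 counted loci in seedling, 2523 were at least 2-fold higher and 3148 at least 2-fold lower in Dp3a, and 79.8% lay within 2-fold. The share of 2-fold loci that were higher was 44.5%, but 33.3% among loci with a gene ID, where 1136 were higher and 2279 lower. The balance depended on the setting, with 52.1% higher at a 4-fold threshold (890 higher and 817 lower) and 1103 higher and 1104 lower with a pseudocount of 5. In leaf the share was 46.1% at 2-fold and 51.1% at 4-fold (378 and 362). Across loci the log2 values of both libraries had a Pearson r of 0.766. GLK5 was listed at 0 in control and at 1269 FPKM in Dp3a seedling, and ACR4 at 0 and 9.88. PDIL5-1 had 33.3 FPKM in control, Laccase-13 had 13.3 and x1 had 18.6, and all of these were listed at 0 in Dp3a seedling. Natterin-4 had 383 and 16.8 and b3gat3 had 31.9 and 0.999.

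The largest ratios of all in seedling again came mostly from loci of about 100 bp without a gene ID. Listed at 0 in control seedling were XLOC_059288 (94433 FPKM in Dp3a), XLOC_015587, XLOC_047038, XLOC_047075 and XLOC_097201 (85848 each), XLOC_017135 (82734), XLOC_047207 (76893) and XLOC_015426 (60557). Listed at 0 in Dp3a seedling were GRMZM2G124409 (22543 FPKM in control), XLOC_046998 (10383), XLOC_015764 (5164), XLOC_059313 (3585), XLOC_081159 (2932), XLOC_015700 and XLOC_070604 (2175 each). In Dp3a seedling 10 loci held 67.0% of the FPKM sum, against 51.6% in control seedling. Loci listed at 0 in 1 library alone, with 1 FPKM or more in each of the other 3, numbered 280 for Dp3a seedling and 82 for control seedling.

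For seedling, 66 loci were called significant in the authors' deposited table. Of these calls in the authors' deposited table, 15 were listed at 0 in control and 51 at 0 in Dp3a, and 24 of the 51 had 1 FPKM or more in Dp3a leaf. The 1 locus called in both tissues in the authors' deposited table, XLOC_092049 on chromosome 8, went opposite ways, listed at 0 in control leaf against 11.2 FPKM in Dp3a leaf and at 2.48 in control seedling against 0 in Dp3a seedling.

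Of the 13 lists with a percentile in seedling, 5 lay outside the central 95% of random lists. Light harvesting had a median log2 ratio of -1.53 (percentile 0.01), with 6 of 6 loci at least 2-fold lower, among them lhcb5 (118 and 24.3 FPKM in control and Dp3a), Cab-m7 (407 and 151) and CP24 (12.4 and 3.49). C4 photosynthesis had a median of -1.22 (percentile 0.11), with 5 of 7 loci at least 2-fold lower, among them rbcS (178 and 63.2) and mdh6 (42.9 and 17.8). Plastid-encoded loci had a median of -1.54 over 29 loci in the same libraries, with 22 at least 2-fold lower. Jasmonate and wound response had a median of -0.79 (percentile 0.00), with 30 of 31 loci below 0 and 14 at least 2-fold lower, among them aos2 (147 and 10.9) and lox6 (362 and 33.9). The anthocyanin pathway had a median of -0.92 (bootstrap interval -2.71 to 1.22, percentile 1.28, 6 loci), or -2.22 with a pseudocount of 0.1 and -1.60 with a filter of 5 FPKM, with the chalcone synthase c2 at 12.7 and 0.824, the flavanone 3-hydroxylase f3h at 6.52 and 0.322, A1 at 1.24 and listed at 0, and R-S at 0.892 and 6.48. Cell cycle and DNA replication had a median of 0.45 (percentile 98.0), with 5 of 6 loci above 0, among them the replicative helicase subunit MCM6 (12.5 and 18.0), the cyclin cyc3 (5.89 and 8.94) and magi81248 (52.1 and 73.5). The gene csh9 was lower at 1 locus (9.83 and 6.17) and slightly higher at another (8.09 and 8.96). Counted as 1 locus per gene ID, a choice made after seeing the data, the cell cycle percentile was 96.95 and the list no longer stood outside. Counted that way, the jasmonate list had a median of -0.54 over 25 loci (percentile 0.06), with 9 at least 2-fold lower. The light harvesting list then had a median of -1.46 over 4 loci (percentile 0.23), with 4 at least 2-fold lower.

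The remaining lists lay inside that range in seedling. DNA methylation and silencing had a median of 0.18 (percentile 92.1), with 10 of 12 loci above 0. Among them were the RNA-dependent RNA polymerase mop1 (9.02 and 22.2 at 1 locus, 5.43 and 6.23 at another) and the chromomethylase met2 (17.1 and 25.8). Centromere and kinetochore had a median of 0.34 (percentile 91.0), with 4 of 4 loci above 0. These were MIS12-1 (2.26 and 3.89), CenpcA (8.43 and 10.5) and the cenH3 loci GRMZM2G157596 (4.77 and 6.53) and GRMZM2G158526 (11.9 and 12.5). Core and linker histones had a median of 0.15 (percentile 50.6, 8 loci), with his2b5 at 171 and 261. The circadian clock had a median of -0.30 (percentile 18.5), with 6 of 6 loci below 0, among them PRR59 (5.47 and 4.23). Heat shock and chaperones had a median of -0.18 (percentile 24.9, 7 loci), with hsp22 at 34.8 and 123, and a filter of 5 FPKM turned that median to 0.21. Defence and pathogenesis-related had a median of 0.23 (percentile 85.1, 8 loci), or 0.11 with a filter of 5 FPKM, with chiI at 12.3 and 3.46. The gene prp2 had 31.1 and 121 at 1 locus and 660 and 715 at another. Cell wall expansion had a median of -0.13 (percentile 15.7, 14 loci), with expB8 at 290.4 and 128. As 1 locus per gene ID, the cell wall median was -0.74 over 11 loci, at percentile 0.17. Nitrate and phosphate uptake had a median of -1.15 (percentile 5.37, 3 loci), or -2.92 with a pseudocount of 0.1, with NRT1.2 at 2.09 and 0.189 and pht1 at 1.15 and 3.96. Of the lists of other tissues, oleosin had 1.14 and 2.05 FPKM, rth3 8.43 and 8.36, Profilin 40.2 and 5.98 and DBB11 15.9 and 18.7.

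Leaf and seedling ratios were set against each other to ask whether Dp3a went with the same differences in both tissues. Across loci, the ratios of the tissues were close to unrelated. Over the 19800 loci counted in both, the log2 ratios had a Pearson r of 0.0530 and a Spearman rho of 0.0339, and loci are not independent replicates. At least 2-fold higher in both were 153 loci, against 31.8 for independent lists, and lower in both were 260, against 91.9. The opposite ways were also above independent lists, with 156 higher in leaf and lower in seedling against 62.9, and 172 lower in leaf and higher in seedling against 46.4. Of the loci with a symbol, 25 were at least 2-fold lower in both tissues and 4 at least 2-fold higher. Among those lower were aos2, lox6, lox10, TIFY28, expB5, expB6, expB8, bHLH116 and Natterin-4, and among those higher were R-S, gst42 and gst41 (54.9 and 133 FPKM in control and Dp3a seedling).

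The loci highest in both tissues were short or carried no gene ID. Listed at 0 in both control libraries were XLOC_023105 (2718 FPKM in Dp3a leaf and 6403 in Dp3a seedling), XLOC_070745 (811 and 2819), XLOC_031355 (713 and 4181), XLOC_037932 (621 and 2443), XLOC_070544 (171 and 305), XLOC_088166 (94.9 and 248), XLOC_070587 (91.0 and 172) and XLOC_059219 (68.7 and 36.4). Listed at 0 in both Dp3a libraries were XLOC_105699 (450.2 FPKM in control leaf and 1069.7 in control seedling), XLOC_070604 (823 and 2175), XLOC_035930 (585 and 357), XLOC_059251 (209 and 319), XLOC_070814 (44.2 and 43.9), XLOC_059352 (37.0 and 44.3) and XLOC_105706 (541 and 23.6). XLOC_088201 belonged with them, with 3601 in control leaf and 267 in control seedling.

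Loci whose span overlaps the de novo domain were examined to ask whether CENH3 chromatin goes with a difference in their expression. The design took normal copies of the region to be present with and without Dp3a, and FPKM does not separate them from a copy on Dp3a. Near-equal values therefore cannot show whether a copy bound by CENH3 is expressed. The most expressed gene, GRMZM2G045275, had 46.8 FPKM in control and 44.9 in Dp3a leaf, and 12.6 and 14.8 in seedling. The locus of GRMZM2G045318 and GRMZM2G342693 had 25.1 and 29.6 in leaf and 3.12 and 5.27 in seedling. A second locus of GRMZM2G045275 and GRMZM2G045318 had 0.510 and 0.719 in leaf and 4.69 and 4.76 in seedling, and GRMZM2G125571 had 1.05 and 0.209 in leaf. Loci without a gene ID among them were XLOC_041060, with 10.9 and 12.6 FPKM in leaf and 3.53 and a listing at 0 in seedling, and XLOC_047343, with 1.15 and 1.54 in leaf and 1.30 and a listing at 0 in seedling.

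Of 25 loci that overlap the domain, 19 had less than 1 FPKM in each of the 4 libraries and 5 were counted in each tissue. Their median log2 ratio was 0.20 in leaf (percentile 84.0 of random lists) and 0.02 in seedling (percentile 62.3). The named loci share a single span, 218975226 to 219182995, which begins left of the domain, so whether each lies inside the domain is not resolved. With the domain called at 3 times the median, the seedling median was 0.52 over 14 loci (percentile 99.5) and the leaf median 0.21 over 16 loci (percentile 97.8), but 9 of the 14 and 11 of the 16 also belong to the flanks of 1 Mb described next.

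The median ratio of loci in the flanks of 1 Mb was above 0 in seedling, while their leaf median lay at 0.00; the difference between the tissues was not tested across plants. The kinetochore gene CenpcA (GRMZM2G114315), at 218621154 to 218631182 in the left flank, had 7.22 and 8.27 FPKM in control and Dp3a leaf and 8.43 and 10.5 in seedling. The flanks held 132 loci. In seedling 50 were counted with a median log2 ratio of 0.29 (bootstrap interval 0.15 to 0.45, percentile 99.99), and 35 of them, 70%, were above 0, against 46.8% of all counted loci, with 5 at least 2-fold higher and 2 at least 2-fold lower. In leaf 49 were counted with a median of 0.00 (-0.15 to 0.10, percentile 62.5). Counted as 1 locus per span, a choice made after seeing the data, the seedling median was 0.23 over 45 spans with 66.7% above 0.

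Expression along chromosome 3 was examined for stretches that stand apart, since Dp3a carries material of that chromosome. The 5 Mb bin with the de novo domain, 215000001 to 220000000, had a median log2 ratio of 0.22 in seedling over 76 loci, rank 8 of 405 bins from the highest, and -0.07 in leaf over 72 loci, rank 316 of 413. These medians use loci with 1 FPKM or more in both libraries, which leaves out loci absent from Dp3a seedling. With 1 FPKM or more in either library, a choice made after seeing the data, the seedling median was 0.08 over 107 loci, rank 64 of 415 bins, and the leaf median -0.08 over 83. The next bin, 220000001 to 225000000, had 0.21 in seedling and -0.08 in leaf by the first measure. On chromosome 3 the bins ranged from -0.16 to 0.25 in leaf and from -0.26 to 0.22 in seedling, and 0 bins in either tissue lay beyond 1.5-fold. Over all chromosomes 1 bin did, on chromosome 6 at 10000001 to 15000000 in seedling, with a median of 1.40 over 19 loci and 1.80 over the 15 with a gene ID. A CENH3 domain of the map, 10350001 to 10550000 at 7.48 times its median, lies in that bin, whose leaf median was -0.02. With loci at 1 FPKM or more in either library, 4 seedling bins and 0 leaf bins lay beyond 1.5-fold. These were the same chromosome 6 bin (1.24 over 46 loci), its neighbour at 15000001 to 20000000 (0.68 over 22), chromosome 1 at 130000001 to 135000000 (1.04 over 12) and chromosome 7 at 60000001 to 65000000 (0.67 over 17).

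**Figure D4:**
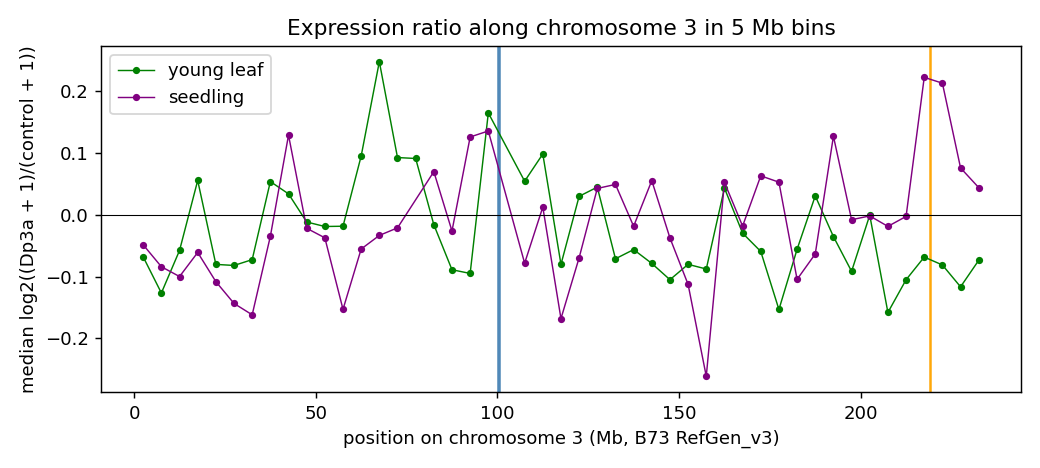
Median log2 ratio of Dp3a over control in 5 Mb bins along chromosome 3, by position in Mb, for leaf (green) and seedling (purple), with the native centromere in blue and the de novo domain in orange. The bin with the de novo domain stands at 0.22 in seedling and -0.07 in leaf.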

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

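The tests on the genes beside the de novo domain below were chosen only after their result was seen; the lists, the bins and the flanks themselves were not.

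Light-harvesting genes, which bind the chlorophyll of the photosystems, drew attention because their loci lay above 0 in leaf and below 0 in seedling: the median log2 ratio of Dp3a over control was 0.25 in leaf and -1.53 in seedling, a seedling minus leaf difference of -1.78, and this difference was not tested. Plastid-encoded loci drew attention in the same way, with medians of 0.69 and -1.54 and a difference of -2.24, also not tested. That difference sets 15 leaf loci against 29 seedling loci. The leaf loci went both ways, with log2 ratios from -3.13 to 4.98, 6 at least 2-fold higher and 2 at least 2-fold lower, and their FPKM sum was lower in Dp3a, 4049.8 against 4573 in control. The chromosome 3 bin that holds the de novo domain had medians of -0.07 in leaf and 0.22 in seedling, a difference of 0.29, not tested either. These medians leave out loci below 1 FPKM in control or Dp3a, and with loci at 1 FPKM or more in either library, a choice made after seeing the data, the seedling median was 0.08. Calls placed on the mitochondrial genome drew attention as a signal outside the comparisons. Over every cytosine with 1 or more reads, 37.8% of CG calls (exact 95% interval 37.0 to 38.6) and 31.2% of CHG calls (30.4 to 32.0) were methylated, against 3.99% and 3.20% on the plastid genome. The library was made from chromatin bound by CENH3, and which DNA these reads came from was not tested. The mitochondrial CG level is a pooled value over unlike cytosines: of 1123 with 4 or more reads, 33.7% stood at 20 percent or less, 10.7% at 80 percent or more and 55.7% between. Of 76 bins of 1 kb, 19 stood at 20 percent or less and 5 at 80 percent or more. The CHH level was 1.15% in mitochondrial and 0.710% in plastid DNA.

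The median log2 ratio of loci within 1 Mb of the de novo domain was 0.29 in seedling, as reported above. An extra copy of the full flanks that acts alike in both tissues is argued against by the leaf median of 0.00 (0.00074, bootstrap interval -0.15 to 0.10), below the seedling interval of 0.15 to 0.45. These intervals cover the spread over loci and not the spread between plants. A copy shorter than the flanks is not covered by this. Loci of the domain called at 3 times had a leaf median of 0.21 (percentile 97.8), and 11 of these 16 lie in the flanks. A scaling of the whole seedling library is argued against by the median of all counted seedling loci, -0.04. The percentile of 99.99 among random lists matched on expression was already reported above and is not a new test. A seedling-specific effect of the Dp3a fragment may remain as a hypothesis, found and tested on the same pair of libraries. A difference in genetic background between the control and Dp3a seedlings was not tested and stays open.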

How the results depend on the processing

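The alternatives that leave out loci without a gene ID, at 0 or under 300 bp, count 1 locus per gene ID or per span, take every locus in the runs, use mean reads per cytosine or the interval file for domains, pick native centromeres in other windows, or take bin loci from either library were chosen after seeing the data. Of 252 values under another setting, 0 changed direction among called results. Counts of loci, domains, densities and correlations across loci could only be labelled as within limits or moved, so the 0 does not cover them. In both tissues more loci were lower than higher at 2-fold, and more were higher than lower at a 4-fold threshold. Of the main results, 95 values stayed within their limits, 55 moved and 3 no longer passed their test. Lists entered this tally by how many stood outside the range of random lists, so the loss of a single list is not among the 3. Such losses were the anthocyanin list in leaf with a pseudocount of 0.1 and the cell cycle list in seedling at 1 locus per gene ID. No paired analysis was possible because each group held 1 library. Reads at the same position and strand could not be counted once, as no strand or read is given; exact repeats of intervals were counted once instead. The expression filter of any value above 0 changes no 2-fold count by construction, since a ratio of 2-fold needs 1 FPKM. The RNA depth is unknown, and 57.4% of cytosines had 1 read, so no single cytosine was compared.

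Stricter settings give fewer loci, and a smaller pseudocount more, by construction. In leaf, against 1287 higher and 1504 lower, a pseudocount of 5 gave 514 and 573, a filter of 5 gave 758 and 964, a 4-fold threshold 378 and 362, loci with a gene ID 700 and 950, and a pseudocount of 0.1 gave 2369 lower. In seedling, against 2523 and 3148, a pseudocount of 5 gave 1103 and 1104, a filter of 5 gave 1567 and 1796, a 4-fold threshold 890 and 817, and loci with a gene ID 1136 higher. In both tissues, against 153 higher and 260 lower, a pseudocount of 0.1 gave 451 lower, a pseudocount of 5 gave 71 and 76, a filter of 5 gave 97 and 129, leaving out loci at 0 gave 76 and 159 with r of 0.0158, and leaving out loci under 300 bp gave 92 higher with r of 0.0315. Loci overlapping the de novo domain had a leaf median of 0.21 with pseudocount 0.1, 0.19 with no filter and 0.21 with the domain at 3 times, and a seedling median of 0.41 with a filter of 5, 0.12 with no filter and 0.52 with the domain at 3 times; the cause was not tested.

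The de novo domain spanned 400 kb at 3 times the median, with 41 domains in all, and 0 kb at 10 times, with 9 domains. By mean reads per covered cytosine it spanned 0 kb at 5 times, with 3 domains on 2 chromosomes, and 400 kb at 2 times. The interval file gave 0 kb and 12 domains. With 20 kb windows the rho of both marks was 0.949, the native CENH3 median 6.27 times, the ph-H2A-T133 median over further chromosome 3 stretches 3.15 times and their number 21, against 4. Against flanks, the de novo domain differed by 6.99 points in CG and -1.10 in CHG at 1 or more reads, by 4.26, -4.60 and -0.218 in CG, CHG and CHH at 8 or more reads, by 6.47 in CG and -0.970 in CHH as the mean of single cytosines, and by 3.67 in CG and -4.51 in CHG with flanks of 500 kb. The native CHG difference of -0.429 at 8 or more reads did not pass the test, nor did the CG difference of 1.20 with native centromeres of 20 kb windows and the CHG difference of -3.19 with those of 100 kb windows. The cause was not tested for any of these.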

Other observations

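The runs of neighbouring loci and the tests on them and on CG methylation in this part were chosen only after their results were seen. On the long arm of chromosome 3, to the left of the de novo domain, a stretch of genes expressed in control seedling was close to absent in Dp3a seedling. Between 215251197 and 216876717, 12 of 20 consecutive loci with 1 FPKM or more in control seedling had less than 10 percent of that in Dp3a seedling, against 5.81% of 22657 such loci in the genome. They include A1, the dihydroflavonol reductase of anthocyanin synthesis (1.24 FPKM and listed at 0), x1 (18.6 and listed at 0), sum1 (1.46 and 0.0437), GRMZM2G125193 (27.2 and 0.0236), GRMZM2G057942 (15.8 and listed at 0) and GRMZM2G000593 (15.6 and listed at 0). The others were GRMZM2G029547, GRMZM2G180815, GRMZM2G316635, XLOC_046457, GRMZM2G464976 and GRMZM2G364528, and 8 of the 12 were listed at 0. The other 8 loci of the stretch were also lower in Dp3a seedling, 3 of them more than 2-fold, GRMZM2G088436 (7.47 and 1.17 FPKM), GRMZM2G088397 (11.4 and 4.87) and GRMZM2G047695 (11.2 and 3.49). GRMZM2G130358 had 66.1 and 38.2, GRMZM2G037431 had 2.72 and 1.93, and XLOC_040972 had 5.71 and 5.35. All genes of this stretch were named after their values were seen, apart from A1 and x1. GRMZM2G057942, x1 and GRMZM2G000593 are among the calls in the authors' deposited table. Counted with every locus, the stretch from 215607989 to 216876717 held 14 low loci of 20.

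The other directions gave runs of fewer loci. Loci low in control seedling reached 8 of 20 on chromosome 1 (115345048 to 118885633), with 24 of 1000 shuffles as high, and loci low in Dp3a leaf reached 5, with 591 of 1000 as high. Loci low in control leaf reached 9 of 20 on chromosome 1 (141278760 to 143639456), with 0 of 1000 shuffles as high.

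Of the explanations for the chromosome 3 run, positions falling together by shuffling are argued against, since the highest of 1000 shuffles within expression strata held 10 low loci and the run holds 12. The run of loci low in control leaf also exceeded every shuffle, so this result is not particular to the chromosome 3 run. The stretch missing altogether from the DNA of the Dp3a leaf plants is argued against as well. Bisulfite calls over the low loci stood at 150 per kb, 0.603 of the density over the other loci of the run. Chromosome 3 as a whole stood at 168 per kb. None of the low loci lacked calls, and the lowest of them stood at 38.3 per kb. A loss of some of the copies is not covered by this. The DNA of the Dp3a seedlings themselves was not examined. Whether Dp3a leaf shows the same loss cannot be told apart from no expression there, since 0 of the low loci had 1 FPKM or more in control leaf. A difference in genetic background between the seedling plants, or an effect of the Dp3a fragment on this stretch, may account for the run, and neither was tested.

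CG methylation was higher in the de novo domain than in its flanks by 6.07 points. Incomplete bisulfite conversion in the domain is argued against by its lower CHH level, a difference of -0.705 points. Selection of deeply covered cytosines as the source of the higher CG level is argued against by 6.99 points at 1 or more reads. The size of the CG difference did depend on coverage, and it was smaller under the stricter read minimum reported above. Ordinary variation between stretches of chromosome 3 remains a candidate explanation, since the domain lay at percentile 79.1 of random placements. A link between CENH3 and CG methylation at this site was not tested, as no methylome of control plants was used here. The CENH3 library may also sample unlike chromatin in the domain and in its flanks.

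In percentage points, the further CENH3 domains of the map differed most in CHG methylation. The densest, on chromosome 6 at 20450001 to 20650000, held 92.1% CG, 45.9% CHG and 1.82% CHH methylation, and the one at 39150001 to 39300000 held 89.3%, 52.1% and 2.43%. The tip of chromosome 10, 1 to 500000, held 92.2%, 66.8% and 2.03%, and the domain on chromosome 4 at 103600001 to 103850000 held 93.8%, 71.1% and 1.74%. Mean coverage was 82.5 and 42.6 reads per CG cytosine in these chromosome 6 domains. It was 13.8 at the tip of chromosome 10 and 10.4 in the chromosome 4 domain. Without an input library, copies of a repeat collapsed in the reference cannot be told apart from CENH3 in such domains.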
